A study of Mus musculus with 4 samples.

How the data were processed

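Gene expression was measured in 4 samples from dorsal dentate gyrus, each from the granule cell layer of female C57BL/6J mice: inner and outer side at 3 months and at 20 to 24 months, each a pool of 8 mice. Per the labels, the sides were cut from 20 µm sections by laser capture microdissection, and 0.6 µg RNA was amplified with the WT-Ovation Pico system and labelled with Cy3. Whether the inner and outer samples came from the same mice is not stated in the sources used here, so the samples were not paired by animal.

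The deposited scanner files hold Cy3 intensity per spot, 44397 features per array. Per the file headers, Agilent Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09 subtracted a background and detrended the spots to give the processed intensity, with surrogate values at the floor; the submitters' processing notes name version 9.5.3. The deposited files also give the mean intensity and the local background median intensity of each spot, without correction, and other columns hold flags for spots that are well above background, saturated or outliers, per the file headers. Probe positions are on build mm9, per the file headers. The 4 arrays carry the same scan time, so scan or slide could not serve as a block.

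A value table deposited by the authors holds log2 values, centred on the median of the 4 arrays in 100% of its 27416 complete rows. Its columns have medians of -0.0133, -0.0084, 0.0082 and 0.0803 for young inner, young outer, senile inner and senile outer. Under the probe names the table gives, its values correlated with the scanner values by only 0.0038 to 0.0102. Of 1065 rows over 4-fold, 1057 (99.2%) matched the 3 differences between arrays of some probe within 0.003 log2, 2 of them that of the probe named; with shuffled differences 0.0939% matched. Probes of 1 gene correlated with r = 0.20 in the scanner files and 0.011 in the value table, over 2761 pairs. The table's scale (log2, 75th percentile) and direction therefore match the scanner files and its probe names do not, and its values were not used by gene.

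The main values were log2 processed intensity minus the 75th percentile over the 43020 non-control spots of each array. Outlier spots (131 to 221 per array) were left out, spots of a probe averaged, and 1 probe kept per gene, the brightest on average; 7195 genes had several probes. Of 39429 probes, 26761 were named by accession and 4453 by symbol through the RefSeq table of assembly GRCm38.p6, used for names alone, and 8215 kept the name in the file; 3517 symbols were updated. Where a gene was not well above background on an array, its value there was replaced, for folds, counts and list medians, by the higher of its own signal and the lowest signal well above background on that array, so such folds are bounds. Of 30068 genes, 21115 were well above background on all 4 arrays and 5160 on none.

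Layer (inner minus outer, age kept in the model) and age (senile minus young, layer kept in the model) were fitted with limma on measured values of genes well above background on at least 2 arrays, with Benjamini-Hochberg adjustment at 0.05. The residual of this fit has 1 degree of freedom, made of the layer-by-age difference and noise. Pairs of arrays were described by the number of genes of at least 2-fold, with no test, over genes well above background on at least 1 of the 2 arrays. Agreement over the disjoint pairs was counted beside n1 × n2 / N for independent lists. The layer-by-age difference was counted at 4-fold. For each of 33 gene lists the median log2 difference was placed among 10000 random lists of the same size drawn from 20 bins of mean signal. The limma p of the genes of each list were also adjusted over the list alone, a count added after the values were seen, with no further adjustment for the number of lists. The comparisons with their other tests, the 33 lists, the alternatives listed below and the naming rule were fixed before the data were examined. The striatal list, the diagonal grouping of arrays and the tests of explanations, except that of other probes, were set later.

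Named genes had a symbol and were well above background and unsaturated on all 4 arrays: for layer and for age, the 12 in each direction with the largest value of the smaller of their 2 log2 differences, and for layer by age the 6 with the largest difference each way. Up to 4 genes per direction with a bound, and up to 4 members per list with the largest mean difference, were added. Of the 60 genes so named outside the lists, 7 had another probe above background, and all 7 such probes went the same way. The genes of the levels figure, Gas1, the striatal genes and the list members named for their normexp calls were chosen after their values were seen. Some genes that fell under these rules are not reported here.

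Alternatives were normexp background correction with offset 50, quantile or median scaling, all 4 arrays or no filter on dim genes, the mean of a gene's probes, eBayes with a trend, a fit without the second factor, folds of 1.5 and 3 (or 2 and 8 for layer by age), means in place of medians, and leaving out each array. The steps were also run on simulated data of 23254 genes, with mean signals from the 4 arrays. The simulated noise was drawn from the layer-by-age differences of genes of like signal on these arrays. There, 89 of 100 genes changed 4-fold and 99 of 100 changed 16-fold between layers were found over 2-fold at both ages. Of the unchanged genes 320 agreed in direction and 305 disagreed, and 100 of 100 lists shifted by 0.5 log2 in the age difference lay outside the central 95%. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.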

Results

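The series asked how gene expression in the granule cell layer of the mouse dentate gyrus differs with position and with age. Adult neurogenesis, the birth of granule neurons from stem cells, takes place at the inner border of this layer, the subgranular zone, which faces the hilus. The outer side faces the molecular layer. Laser capture microdissection of 20 µm coronal sections gave RNA of the inner and the outer side of the dorsal dentate gyrus of female C57BL/6J mice at 3 months (young) and at 20 to 24 months (senile). Each of the 4 samples was a pool of 8 mice hybridised to 1 one-colour Agilent array, so every group had 1 array and no replicate. Of the 43020 non-control spots, 76.2% were well above background on the young inner array, 75.7% on the young outer, 75.6% on the senile inner and 77.5% on the senile outer array. The 75th percentile of the processed signal was 435, 426, 386 and 418 in the same order, and 0 spots were saturated. Repeat spots of 1 probe differed by a median SD of 0.061 to 0.069 log2, an error of printing and scanning that leaves out the spread between mice. Of 30068 genes, 23254 were well above background on at least 2 arrays. The number of arrays limits the precision of all values, and log2 differences stand for 1 array against another unless a mean is named.

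Most interneuron genes, and a smaller part of the genes of mossy cells and of CA pyramidal neurons, were higher in the inner than in the outer sample at both ages. The counts were 20 of 25 interneuron genes, with 1 lower at both ages, 8 of 17 mossy cell and hilus genes, with 0 lower, and 12 of 26 CA field pyramidal neuron genes, with 3 lower. The smaller shares were not particular to neurons. Oligodendrocyte genes gave 12 of 24, with 2 lower, and endothelial and mural genes 12 of 24, with 5 lower. Astrocyte genes gave 8 of 24, with 9 lower, and microglia genes 1 of 24, with 6 lower. Cyp26b1, which degrades retinoic acid and belongs to the mossy cell and hilus list, was 29.2-fold higher in the young and 21.0-fold higher in the senile inner sample (probe at mm9 chromosome 6, 84521952 to 84522011). Neurod6, a transcription factor of pyramidal neurons, was 20.2-fold and 14.8-fold higher, and Sst, the peptide somatostatin of a class of interneurons, 8.50-fold and 13.1-fold. Eomes, a transcription factor of the dividing neuronal progenitors, was 10.1-fold higher in the young inner and 5.80-fold higher in the senile inner sample. Other genes higher on the inner side at both ages were Ldb2, a cofactor of LIM transcription factors, with 41.7-fold and 20.6-fold, Neto2, an auxiliary subunit of kainate receptors, with a mean log2 difference of 3.36, and the peptide genes Nmb, with 5.99-fold and 7.13-fold, and Adcyap1, with 6.47-fold and 5.47-fold. Gprin3, Rgs12 and Prrg4 were also higher on the inner side, by at least 5.62-fold at either age. Vmn2r112, a vomeronasal receptor with many near-identical relatives, had a mean 9.12-fold excess that cannot be assigned to it with certainty. With normexp background, which draws low signals together, the mean log2 differences were 3.00 for Cyp26b1, 2.36 for Neurod6 and 1.31 for Eomes, and all 12 genes named as higher inside stayed at least 2-fold.

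Fewer genes were higher on the outer side at both ages, and by less. Slc25a34, of the mitochondrial carrier family, was 4.71-fold higher in the young and 9.96-fold higher in the senile outer sample. Tnfsf9, the ligand of the costimulatory receptor 4-1BB, was 9.40-fold and 4.51-fold higher, and Agmat, the enzyme agmatinase, 8.64-fold and 3.95-fold. Ptprb, a phosphatase of vascular endothelium, was 3.61-fold and 8.69-fold higher, Hsd3b7, an enzyme of bile acid synthesis, 5.29-fold and 3.73-fold, and the kinase gene Eif2ak4 3.50-fold and 5.74-fold. Abca9, Acsbg3, Gse1, Sap25 and Cxcl5 were also higher outside, with mean folds of 3.06 to 4.86. With normexp background 10 of the 12 genes named as higher outside were under 2-fold in the mean, with log2 differences of -0.49 for Slc25a34, -0.36 for Tnfsf9, -0.54 for Agmat and -0.17 for Cxcl5, while Hsd3b7 stood at -1.19 and Ptprb at -1.03. Tmem200a, Nfkbie, Mgat4c and Pcdh18 were well above background on both inner arrays and on neither outer array, at least 11.1-fold, 10.9-fold, 8.52-fold and 8.50-fold higher inside. Fgl1, Syne3, Gbp3 and Vmn2r56 showed the opposite, at least 7.40-fold, 6.10-fold, 5.05-fold and 4.33-fold higher outside.

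**Figure D1:**
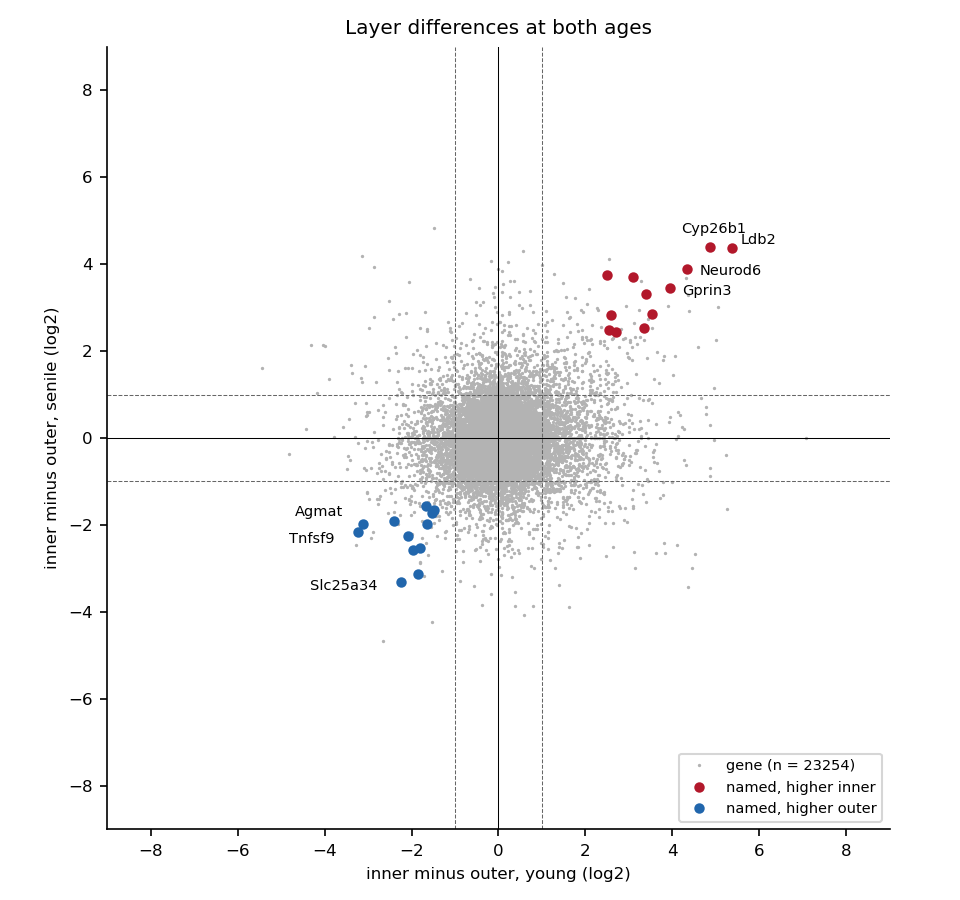
Each point is a gene (23254), with its inner minus outer log2 difference in the young pair on the x axis and in the senile pair on the y axis; dashed lines mark 2-fold. The 12 genes named as higher inner lie in the upper right and the 12 named as higher outer in the lower left. Cyp26b1, at 4.87 and 4.39, leads the inner genes by the smaller of the 2 differences, and Ldb2 lies at 5.38 and 4.36.

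In numbers, 289 genes were at least 2-fold higher and 150 at least 2-fold lower in the inner sample at both ages, against 71.9 and 42.5 for independent lists; with normexp background these genes over 2-fold between layers at both ages were 80 higher and 3 lower. Against these 439 genes of 1 direction stood 324 genes that were 2-fold in opposite directions at the 2 ages. The figure for independent lists takes every gene as equally likely to pass 2-fold. Dim genes passed more often in both pairs, so that figure is too low for noise. In the simulated data, which used no floor for dim signals, 320 unchanged genes agreed in direction and 305 disagreed. Across 22889 genes, which are not independent replicates, the young and senile layer differences correlated with r = 0.11. Among the brightest tertile of genes 22 had the same and 2 the opposite direction, and in the dimmest 252 and 235. The additive limma fit over the 4 arrays called 0 genes at an adjusted p under 0.05 for the layer, with a smallest adjusted p of 0.560, while 1446 genes had an unadjusted p under 0.05 against 1162.7 by chance. With 1 residual degree of freedom the same fit called 0 of 100 simulated genes that differed by 16-fold; with normexp background correction it pooled the spread of all genes and called 172 genes, 163 higher and 9 lower inside, among them 13 of the 24 named. That correction also moved the median layer difference of all genes from -0.05 to 0.15.

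The gene lists fixed beforehand set these genes in groups, each list's median given with its place among 10000 random lists of like signal. The 25 GABAergic interneuron genes had a median inner minus outer log2 difference of 1.29 in the young and 1.32 in the senile pair, above all random lists. Sst, Vip, Tac1 and Htr3a led them, Vip with 3.65 and 1.97 and Htr3a, a serotonin receptor subunit, with 1.56 and 3.24. Mossy cell and hilus genes had medians of 0.77 and 0.40, with Cyp26b1, Rgs12, Drd2 and Nmb in front, and CA field pyramidal neuron genes 0.58 and 0.43. Drd2 and Tac1 also belong to the striatal list. Their log2 signals were 1.94 and 1.31 on the young inner and -0.24 and -0.52 on the senile inner array. Mature granule neuron genes were lower inside, with medians of -0.42 and -0.32, and Tdo2, Cdh8, Dsp and Pitpnm2 were the furthest out, Tdo2 with -1.32 and -0.26. Dendritically localised mRNA genes also had lower inner values at both ages, -0.22 and -0.26, led by Ddn, the gene of dendrin, with -0.88 and -0.71. GABA-A receptor genes had medians of -0.22 and -0.34, below the central 95% of random lists only in the senile pair, although Gabra3 was higher inside by 1.93 and 1.55. Adjusted over the list alone, limma called 13 of the 25 interneuron genes for the layer, 8 of 28 neuroblast and immature granule neuron genes and 4 of 17 mossy cell and hilus genes, each higher inside, among them Sst, Npy, Gad2, Eomes, Gap43 and Cyp26b1. Over all 33 lists, 8 held such genes, 30 different ones, while the adjustment over all genes gave 0. In the layer mean over both ages, 15 lists lay above and 4 below the central 95% of random lists, against 1.65 for lists of unrelated genes. Genes of 1 list can move together with the cells captured, and some lists share genes. The 1.65 is therefore not a chance count for these lists. In the simulated age difference, 9 of 100 lists without a shift lay outside; the layer was not simulated for lists.

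The young pair sets the inner against the outer array of young mice, without replicates. In it the lists of neurogenesis genes were higher inside, but not they alone. Of the 33 lists, 12 lay above the central 95% of random lists, and interneuron genes had a larger median, 1.29. Cell cycle genes had a median inner minus outer log2 difference of 1.07, with 11 of 21 at least 2-fold higher inside and 0 lower, led by Birc5, a gene of chromosome segregation, with 4.17 and the proliferation marker Mki67 with 2.92. Radial glia and neural stem cell genes had a median of 0.78, with 8 of 18 at least 2-fold higher, led by the transcription factor Pax6 with 2.99. Neuroblast and immature granule neuron genes had a median of 0.84, with 12 of 28 at least 2-fold higher, among them Eomes with 3.34, Gap43 with 2.62 and Cd24a with 1.91. All 3 medians lay above all random lists. In the same array, striatal projection neuron genes, a list written after the values were seen, stood a median 1.28 log2 above the mean of the other 3 arrays, above all random lists, and 20 of the 27 measured were highest there, while Drd1 and Pde10a stood only 0.50 and 0.22 above. Adora2a, an adenosine receptor of striatal neurons, had a log2 signal of 1.87 there and -1.52 on the young outer array.

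Further lists differed within the young pair. Higher on the inner side were endothelial and mural genes (median 0.37), complement and MHC class I genes (0.36), disease-associated microglia and phagocytosis genes (0.35), cell senescence genes (0.42), cholesterol synthesis genes (0.29) and axon guidance and semaphorin genes (0.12). Lower on the inner side were meninges, ependyma and choroid plexus genes (-0.33), potassium channel genes (-0.22) and ionotropic glutamate receptor and postsynaptic density genes (-0.21). These 9 lists lay outside the central 95% of random lists. For young inner against young outer, 1787 genes of 23760 were at least 2-fold higher and 1122 lower inside, and with normexp background, which moved the median of all genes in this pair from -0.01 to 0.28, 1050 and 73. Without replicates, these counts have no test.

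In the senile pair, interneuron genes had a median close to that of the young pair, mossy cell and hilus genes a median of 0.40 beside 0.77, and the neurogenesis lists medians near 0. Medians of radial glia and neural stem cell genes (0.00), cell cycle genes (0.00) and neuroblast and immature granule neuron genes (0.02) lay within the central 95% of random lists, although Eomes, Gap43, Cd24a and Sema3c stayed above 2-fold inside, with 2.54, 2.28, 2.94 and 2.89. Of the neuroblast and immature granule neuron genes, 8 of 28 were at least 2-fold higher and 0 lower inside, and the list stood at percentile 94.5. Oligodendrocyte genes, which encode proteins of myelin, had a median of 0.75 inside, above all random lists, led by Aspa with 3.45, Mag with 1.53, Mobp with 1.43 and Opalin with 1.25. Presynaptic vesicle genes had a median of 0.17, led by Slc17a6, the vesicular glutamate transporter of subcortical and hilar neurons, with 1.88. Lower inside were interferon response genes (-0.37), microglia genes (-0.31) and immediate early genes (-0.29). Astrocyte genes (-0.18), oligodendrocyte precursor genes (0.13), neuropeptide and neurotrophic factor genes (-0.22) and Wnt signalling genes (0.01) lay within the central 95%. For senile inner against senile outer, 1192 genes of 24037 were at least 2-fold higher and 1135 lower inside, with no test, and with normexp background 312 and 109.

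Between the ages, genes lower in senile tissue on both sides of the layer included markers of immature neurons. Of the 28 neuroblast and immature granule neuron genes, 26 were lower inside and 21 outside, and most other genes named here belong to no neurogenesis list. Cd24a, a surface glycoprotein of neuroblasts, was 17.1-fold lower in the senile inner and 34.9-fold lower in the senile outer sample (probe at mm9 chromosome 10, 43303706 to 43303765). Nr2f2, a nuclear receptor of some interneurons and vessels, was 16.8-fold and 8.52-fold lower, and the deubiquitinase gene Usp43 14.9-fold and 12.1-fold. Ptx3, a secreted pentraxin, was 9.02-fold and 6.76-fold lower, Cxcr4, the receptor of the chemokine Cxcl12, 6.29-fold and 5.81-fold, Angpt1, the vessel growth factor angiopoietin 1, 5.33-fold and 9.48-fold, and Sstr2, a somatostatin receptor, 5.74-fold and 4.99-fold. Samd5, Car8 and Csrp2 were lower by at least 5.11-fold on either side. The tubulin gene Tuba1c, with a mean log2 difference of -2.83, has close relatives and remains uncertain. Igfbpl1, a gene of neuroblasts, was at least 7.50-fold lower, and Rasef and Slc35d3 at least 8.63-fold and 7.48-fold, being well above background on both young arrays and on neither senile one. With normexp background all 12 genes named as lower in senile tissue stayed at least 2-fold lower, Cd24a with -2.93 and Sstr2 with -1.11.

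Higher in senile tissue on both sides were Epha10, an ephrin receptor, by 7.46-fold inside and 5.96-fold outside, Rph3al, an effector of Rab proteins in secretion, by log2 differences of 2.49 and 3.33, and Fancb, a gene of DNA crosslink repair, by 5.99-fold and 5.89-fold. Wnt5b, a secreted Wnt ligand, was 9.49-fold and 3.88-fold higher, the ubiquitin ligase gene Dtx2 4.60-fold and 7.93-fold, and Depp1 5.56-fold and 5.84-fold. Vpreb1, Cep112, Tssk2, Agbl4, Dach2 and Zscan20 followed with mean folds of 3.96 to 9.34. With normexp background 7 of the 12 genes named as higher in senile tissue were under 2-fold, with log2 differences of 0.92 for Epha10, 0.59 for Fancb, 0.48 for Depp1, 0.74 for Dtx2, 0.45 for Tssk2, 0.30 for Agbl4 and 0.27 for Dach2, while Rph3al stood at 2.01 and Wnt5b at 1.35. Nlrp5, Alpl, Col10a1 and Cntnap4 were well above background in senile tissue alone, at least 8.30-fold, 7.79-fold, 7.71-fold and 5.66-fold higher.

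**Figure D2:**
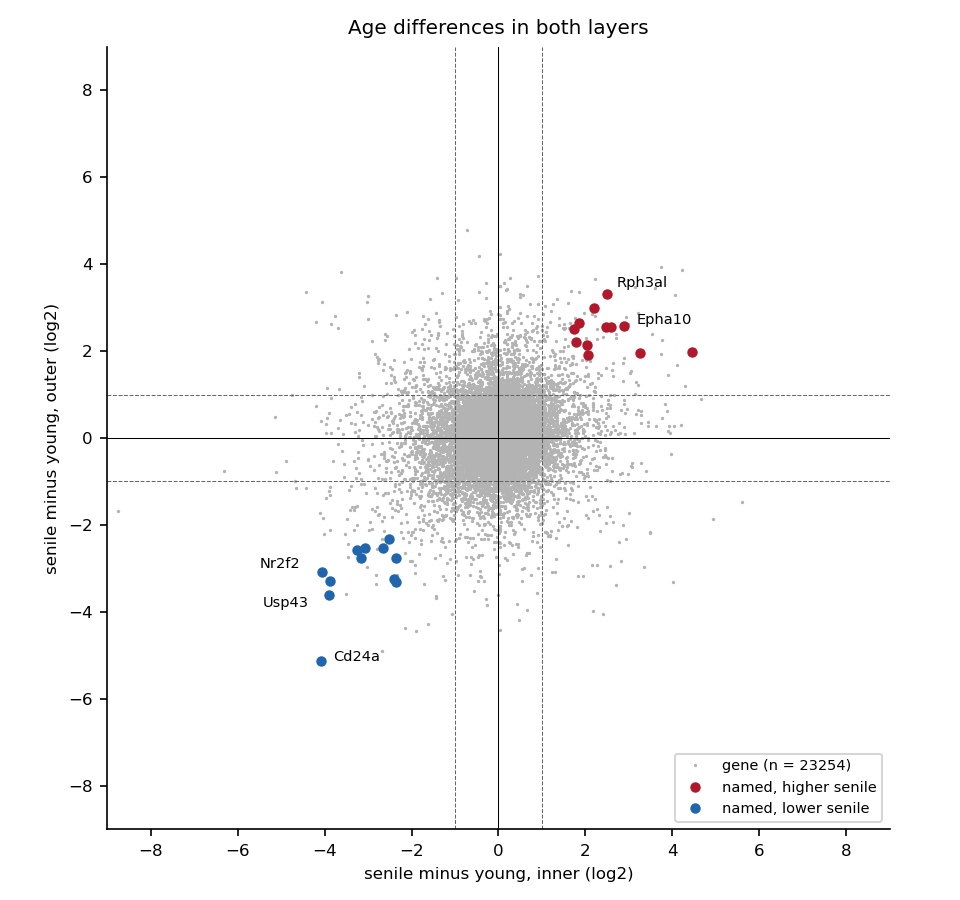
Each point is a gene (23254), with its senile minus young log2 difference in the inner pair on the x axis and in the outer pair on the y axis; dashed lines mark 2-fold. Cd24a lies at -4.09 and -5.12, and the 12 genes named as higher in senile tissue lie in the upper right.

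Over both sides, 215 genes were at least 2-fold higher and 281 at least 2-fold lower in senile tissue, against 57.9 and 66.4 for independent lists, and 299 genes went in opposite directions. Here too the figure for independent lists takes every gene as equally likely to pass 2-fold, so it is too low for noise. These age counts were not simulated. With normexp background the genes over 2-fold between ages in both layers were 17 higher and 60 lower. The inner and outer age differences correlated with r = 0.13 across 22861 genes. In the brightest tertile 27 genes had the same and 3 the opposite direction. The limma fit called 0 genes at an adjusted p under 0.05 for age, with a smallest adjusted p of 0.661, and 1621 genes had an unadjusted p under 0.05 against 1162.7 by chance. With normexp background it called 143 genes, 39 higher and 104 lower in senile tissue, among them 16 of the 24 named, while the median age difference of all genes moved from 0.06 to -0.11.

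**Figure D3:**
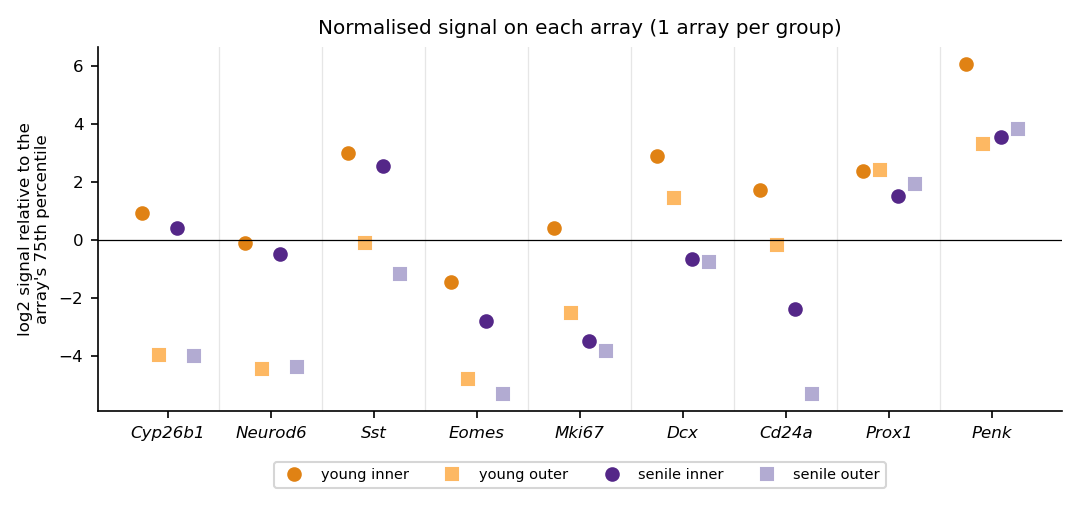
Log2 signal relative to the 75th percentile of the array (y axis) for 9 genes on the 4 arrays, 1 point per array, with no error because each group had 1 array. Dcx stood at 2.90 and 1.46 on the young inner and outer arrays and at -0.64 and -0.75 on the senile ones, while Prox1 lay between 1.53 and 2.41.

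As groups, the neurogenesis lists were lowest on the inner side. Radial glia and neural stem cell genes had a median senile minus young log2 difference of -1.08 inside and -0.27 outside, led by the transcription factor gene Tfap2c with -4.05 and -1.83 and by Wnt8b with -2.98 and -2.11. Neuroblast and immature granule neuron genes had medians of -0.76 and -0.39, led by Cd24a, Dpysl3 with -3.88 and -2.12, Igfbpl1 and the migration protein gene Dcx with -3.54 and -2.21. These 4 medians lay below the central 95% of random lists. Cell cycle genes had a median of -0.65 inside, below all random lists, and 0.13 outside, within the central 95%, with Mki67 at -3.88 and -1.31. Adjusted over the list alone, limma called 1 of the 28 neuroblast and immature granule neuron genes for age, Cd24a, which fell, and among all 33 lists 1 other gene, Gabra3, which was lower as well. Over the 3 lists, 61 of 67 genes were lower in senile tissue inside and 41 of 67 outside. The inner values rest on the young inner array, where striatal projection neuron genes were high; the outer values do not. Prox1, the identity gene of granule neurons, differed by -0.87 inside and -0.46 outside.

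Other lists differed in a less uniform way between the ages. Ribosomal protein genes had medians of 0.22 inside, above all random lists, and 0.15 outside, within the central 95%, and 32 of 37 were higher in senile tissue inside. Astrocyte genes were lower, with -0.43 and -0.13, as were dendritically localised mRNA genes, with -0.26 and -0.23. Immediate early genes, induced by neuronal activity, had a median of 0.08 inside and 0.38 outside, the latter above the central 95%, led by Fos with 0.94 and 2.23. Oligodendrocyte genes had -0.01 inside and -0.48 outside, oligodendrocyte precursor genes -0.12 and -0.35, and mature granule neuron genes 0.12 and -0.31; only the outer values lay below the central 95%. Lower inside alone by that measure were GABAergic interneuron (-0.26), mossy cell and hilus (-0.26), CA field pyramidal neuron (-0.26), Wnt signalling (-0.28), axon guidance and semaphorin (-0.17) and neuropeptide and neurotrophic factor genes (-0.17). Lower outside alone were presynaptic vesicle genes (-0.26), ionotropic glutamate receptor and postsynaptic density genes (-0.13) and potassium channel genes (-0.11). For the mean over both sides, interferon response genes had a median of 0.29, at percentile 98.8 of random lists, and with normexp background -0.15, at percentile 93.1, where the median of all genes was -0.11 (gene list interferon response, age). The median of all genes itself was 0.12 higher in the senile outer than in the young outer array, and 0.10 lower in the senile inner than in the senile outer array.

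Several lists stayed within the central 95% of random lists in all 4 pairs of arrays. Senile minus young, inside and outside, the medians were 0.18 and 0.12 for blood genes, 0.02 and 0.07 for glucocorticoid-responsive genes, 0.07 and 0.05 for stress and heat shock genes, 0.05 and 0.04 for oxidative phosphorylation genes and -0.10 and 0.06 for circadian clock genes. Lists of inflammation and ageing also stayed within it between the ages, with 0.01 and 0.22 for microglia genes, 0.08 and 0.20 for complement and MHC class I genes, -0.01 and -0.01 for disease-associated microglia and phagocytosis genes and -0.23 and -0.01 for cell senescence genes. So did endothelial and mural genes, with -0.07 and 0.02, cholesterol synthesis genes, with -0.10 and 0.03, GABA-A receptor genes, with -0.07 and 0.13, and meninges, ependyma and choroid plexus genes, with 0.12 and -0.01. For senile inner against young inner, 1177 genes of 23740 were at least 2-fold higher and 1604 lower, and for senile outer against young outer 1447 of 24029 higher and 1211 lower. With normexp background the inner counts were 98 and 679 and the outer 251 and 274, and the median of all genes was -0.25 in the inner and 0.08 in the outer pair.

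**Figure D4:**
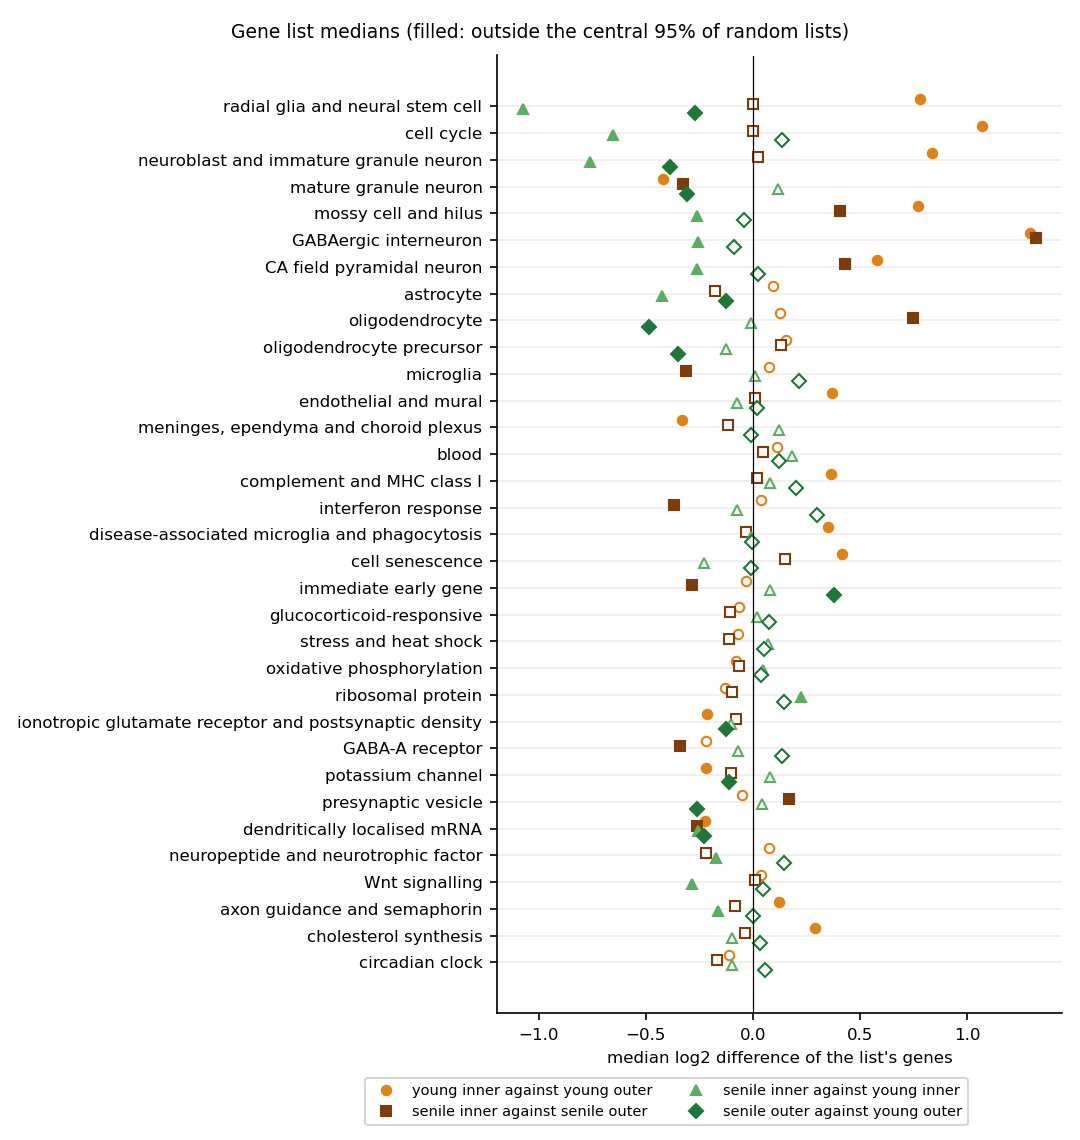
Median log2 difference of each of the 33 gene lists (x axis) in the 4 pairs of arrays, with a filled symbol where it lay outside the central 95% of random lists. GABAergic interneuron genes stand furthest right in both layer pairs (1.29 and 1.32), and radial glia and neural stem cell genes furthest left in the inner age pair (-1.08).

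The layer difference itself was set against age by subtracting the young from the senile inner minus outer value. Of 23254 genes, 648 had an inner excess at least 4-fold larger in young tissue and 409 at least 4-fold larger in senile tissue, with no residual left for a test. The median of all genes in this difference was -0.08, with quantile normalization -0.007 and with normexp background -0.31. The balance of the 2 counts was not set apart from this shift. Cell cycle genes had a median of -0.72, radial glia and neural stem cell genes -0.49 and neuroblast and immature granule neuron genes -0.35, all below the central 95% of random lists, as were astrocyte genes with -0.26. Oligodendrocyte genes had a median of 0.51, CA field pyramidal neuron genes 0.28, presynaptic vesicle genes 0.21 and potassium channel genes 0.18, all above it. The CA field pyramidal neuron list's own layer median was not larger in senile tissue, with 0.58 in the young and 0.43 in the senile pair. Of its 26 genes 15 changed upward and 11 downward, 5 and 6 of them by at least 2-fold, so its direction is not settled. Penk, the gene of enkephalin, had a log2 signal of 6.09 on the young inner array and 3.33 to 3.83 on the other 3, and belongs to the striatal list as well. Some genes with large differences had opposite directions at the 2 ages: Msx2, a homeobox gene, was 22.0-fold higher inside in young and 7.89-fold higher outside in senile tissue, and Efna1, an ephrin, was 43.8-fold higher outside in young and 3.07-fold higher inside in senile tissue. Their layer-by-age log2 differences of -7.44 and 7.07 were -3.38 and 3.87 with normexp background. The share of genes over 4-fold was 9.58% in the dimmest, 3.77% in the middle and 0.284% in the brightest tertile of signal.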

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

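Of the tests in this part, that of other probes was set before its result was seen, and all others after it. Each weighing below is of arrays without replicates.

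For 11 genes given here the layer difference had another sign at the 2 ages, and the change was not tested. The senile minus young layer difference (log2) was -7.44 for Msx2, -6.57 for Fndc9, -5.62 for Tfap2d, -5.10 for Scel, -4.99 for P2ry1 and -4.71 for Fam205c. It was 7.07 for Efna1, 6.80 for Frrs1, 5.67 for Rnf125, 5.64 for Npepl1 and 4.38 for Emilin2. For P2ry1 and Tfap2d the senile difference was small, -0.04 and -0.39, so these lacked the young difference and did not turn. These genes were picked for the size of the change. With normexp background the changes were smaller, with -3.38 for Msx2, 3.87 for Efna1 and 2.40 for Frrs1. Fam205c (-1.96), Rnf125 (1.81), Npepl1 (1.55) and Emilin2 (0.80) then fell under 4-fold. Low signals enter these differences, as with -5.45 for Msx2 on the young outer and -5.38 for Emilin2 on the senile outer array. A candidate explanation for such genes in general is noise of low signals before labelling, from few captured transcripts: the share of genes over 4-fold was 9.58% in the dimmest and 0.284% in the brightest tertile, as this needs. Noise or background handling after labelling would give the same fall, so the shares do not tell these apart. A faulty probe per gene was asked of 101 genes over 4-fold with another probe above background: in 63 (62.4%, exact 95% interval 52.2% to 71.8%) the next brightest probe went the same way. In 29 of the 101 it did so by at least 2-fold. The 62.4% lies between 1 in 2 and the 3 of 4 set as bound, so the share of such genes stays open, as does an effect of age, untested. None of the 11 genes above had another probe above background on all 4 arrays, so this test does not cover them.

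Interneuron genes were higher in the inner array at both ages. Under 4 scalings or background corrections the interneuron list stood 0.761 to 1.35 log2 above the median of all genes. A constant scaling of an array cancels in this distance, so only quantile scaling and normexp could have changed it. The list stayed above all genes under these too, which argues against such scaling. Noise of low signals is argued against as well: the list's 11 members in the brightest tertile had a median of 0.829, above all 10000 random lists. Interneurons and other hilar neurons captured with the inner side remain a candidate source: mossy cell and hilus genes, a list with no gene in common with the interneuron list, had a senile inner minus outer median of 0.40, at percentile 99.9 of random lists, although only 8 of 17 were higher inside at both ages, with 0 lower. In the senile pair oligodendrocyte genes (0.75) and CA field pyramidal neuron genes (0.43) also lay above all random lists. The mossy cell and hilus value is therefore not particular to hilar neurons. Of the 25 interneuron genes, 24 are also above background on both outer arrays, and 3 belong to another list. Sst had log2 signals of 3.00 and 2.56 on the inner arrays and -0.09 and -1.15 on the outer arrays. Position within the layer itself stays open, untested.

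Stem cell, cell cycle and immature neuron genes had a median inner minus outer difference of 0.798 in the young and 0.00077 in the senile pair over 67 genes, although 8 of 28 immature neuron genes stayed at least 2-fold higher inside in the senile pair. For noise of low signals, the 60 members above background on all 4 arrays were taken. Their layer difference was lower in senile tissue by a median of -0.472, below all random lists. These are 60 of the same 67 genes, and 655 of the 1057 genes over 4-fold in layer by age passed this filter as well. The filter thus does not set low signals apart, and their noise stays undecided. Less hilus-side tissue in the senile inner sample cannot be told apart from an effect of age: the interneuron list's change lay above that of these genes by 0.446, with a bootstrap 95% interval of -0.159 to 0.978 that includes 0. The bootstrap redrew the genes of each list, so its interval leaves out the spread between mice, captures and arrays. Mossy cell and hilus genes had a median change of -0.31, within the central 95% of random lists, beside -0.48 for the 67 genes. Tissue of another region in the young inner sample also cannot be told apart: 27 striatal projection neuron genes stood a median 1.28 log2 above the other 3 arrays there, with Penk at 6.09, Ppp1r1b at 3.98 and Adora2a at 1.87, but the list was written after some of these values were seen. For 20 genes whose values had not been seen when they were first named, the median was 0.45, at percentile 99.97 of random lists. Of these, 12 were highest on the young inner array. That is more than an even share among the 4 arrays, but under the 3 of 4 set as bound after values were seen. Drd1 (0.50), Pde10a (0.22), Rarb (0.19), Pde1b (0.18) and Six3 (-0.27) stayed low. Of the 27, 25 are above background on both outer arrays, and 3 belong to a list fixed beforehand. In the outer arrays, which such tissue would not touch, the 67 genes had a median senile minus young difference of -0.117, below all random lists. There oligodendrocyte (-0.48), oligodendrocyte precursor (-0.35) and mature granule neuron genes (-0.31) were lower by more, and cell cycle genes stood at 0.13. The lower outer value is therefore not particular to the 67, and age stays open, untested.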

How the results depend on the processing

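Agreement between pairs was lowest at low signal over background: over layers, 252 genes went the same and 235 the opposite way in the dimmest tertile, and 22 and 2 in the brightest. The diagonal grouping of the arrays was added after seeing the data. Counts were set against the main ones at 1.5 times. Quantile and median scaling and the mean of a gene's probes moved none of the counts by that much, and eBayes with a trend and the fits with no replicate block (age or layer left out of the model) kept 0 calls. No paired analysis was possible because the labels give no shared replicate numbers beyond 1 array per group. The value table was not run by gene because its probe names do not match, and no slide block was fitted because all arrays share 1 scan.

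Normexp background gave 172 calls for layer difference over both ages and 143 for age difference over both layers, where 1 prior spread was shared by all genes; with layer as the residual the diagonal grouping, which is neither layer nor age, gave 13 calls and age 55, and with age as the residual the diagonal gave 31 and layer 129. Normexp also gave 1123 genes for young inner against young outer, 421 for senile inner against senile outer, 777 for senile inner against young inner, 525 for senile outer against young outer, 83 for genes over 2-fold between layers at both ages (7 opposite), 77 for genes over 2-fold between ages in both layers (15 opposite) and 83 for layer by age. The offset draws low signals together, so fewer genes pass a fold, and the balance of directions moved with the median of all genes, 0.28 in young inner against young outer.

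With genes well above background on all 4 arrays the counts were 1916 for young inner against young outer, 1505 for senile inner against senile outer, 1756 for senile outer against young outer and 655 for layer by age. With no filter they were 4445, 4137, 4396 for senile inner against young inner, 4520, 798 for genes over 2-fold between layers at both ages, 894 for genes over 2-fold between ages in both layers and 2467. At 1.5-fold the pairs in the same order gave 6000, 5812, 5932 and 6392 and the counts over both pairs 1263 and 1460; at 3-fold 1329, 845, 1181, 1049, 127 and 148. Layer by age gave 3992 at 2-fold and 325 at 8-fold.

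Of the list medians for layer and age, 95 of 726 under the alternatives changed sign, 76 of them of lists within the central 95% of random lists in the main values, 12 of these with normexp. Only the other 19 are given by value. With normexp these were gene list interferon response, age (-0.15) and gene list presynaptic vesicle, layer (-0.00295), where the medians of all genes were -0.11 and 0.15. Both thus went from above to below the median of all genes, while among random lists of like signal they stood at percentiles 93.1 and 97.3. For the rest the cause was not tested: with no filter gene list Wnt signalling, layer was -0.0192. Leaving out an array leaves 1 pair and no test. Without a young or a senile array, gene list disease-associated microglia and phagocytosis, layer was -0.0340 or 0.352, gene list axon guidance and semaphorin, layer -0.0820 or 0.12, gene list cholesterol synthesis, layer -0.0370 or 0.291 and gene list presynaptic vesicle, layer 0.170 or -0.0497. Without an inner or an outer array, gene list cell cycle, age was 0.134 or -0.653, gene list Wnt signalling, age 0.0464 or -0.283, gene list mature granule neuron, age -0.307 or 0.115 and gene list interferon response, age 0.300 or -0.0743. Apart from these 19, 252 medians moved and 455 did not, sign changes included in both. For named genes 73 values moved, 287 did not and 0 turned. These genes had to be well above background on every array, so another filter on dim genes could not move their values. They were also picked for large differences, so the 0 that turned says little about stability.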

Other observations

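The striatal list was written and tested only after the values were seen. Several markers of striatal projection neurons were high on the young inner array. The transcription factor gene Meis2 exceeded the mean of the other 3 arrays there by 5.61 log2 (as a bound), the adenosine receptor gene Adora2a by 3.57, the dopamine receptor gene Drd2 by 3.28 and Ppp1r1b, the gene of the phosphatase inhibitor DARPP-32, by 2.96. Other genes of this list did not follow, with 0.50 for the dopamine receptor gene Drd1, 0.22 for Pde10a and -0.27 for Six3. Of the 27 measured genes 14 were more than 2-fold above the mean of the other 3 arrays on the young inner array, 1 on the young outer, 0 on the senile inner and 1 on the senile outer array.

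Under normexp background, genes called by limma fell into the fixed lists as follows. For the layer, 11 interneuron genes were higher inside (among them Sst, Cnr1, Npy, Tac1, Slc32a1, Htr3a, Dlx1, Vip, Dlx6os1 and Gad2) and 0 lower. The immature neuron list gave 7 higher inside (Gap43, Stmn2, Sema3c, Cd24a, Eomes, Fxyd6 and Dlx2) and 7 lower in senile tissue (Cd24a, Dcx, Camk4, Dpysl3, Sema3c, Hmgb3 and Igfbpl1). The 2 cell cycle genes lower in senile tissue were Mki67 and Rrm2. Gas1, with the smallest adjusted p for both layer and age, owes its place to 1 probe that was bright on the senile inner array alone, which shows that this pooled spread also lets single arrays through. In the brightest probe of Gas1 the mean layer difference was 0.20. Of the calls, 117 of 172 for layer and 101 of 143 for age had at least 2-fold in 1 direction in both pairs of the main values.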
